A study of Homo sapiens with 16 samples.

How the data were processed

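Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in PANC-1, an established human pancreatic ductal adenocarcinoma cell line. The 16 libraries fall into 8 groups of 2, labelled replicates 1 and 3. The groups combine 2 arms (a control labelled scr, and knockdown of SIK3, salt-inducible kinase 3), untreated cells or cells given 100 ng/ml of recombinant human TNF, and 4 h or 24 h. The labels differ on how SIK3 was lowered: the treatment protocol names siRNA and untreated controls, and the series' design text names shRNA and a vehicle. The arms are called control and knockdown cells here. Nothing in the labels says that replicates came from separate cultures, so p-values of comparisons between libraries measure only the spread between these samples, which may be technical. Fisher's tests of how many regions lie near genes or other peaks take regions as units. Regions are not replicates, so those p-values describe these regions only.

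The authors deposited 1 list of called peaks per library. Per the submitters' processing notes, Bowtie2 (version 2.3.3), HOMER (version 4.10) and bedtools were used with genome build hg38. The role of each tool, the peak-calling settings, any shift of read ends for the transposase and what was intersected with what are not given in the sources used here. Each deposited list holds a chromosome, start, end, name and score. The deposited score was 1000 for every peak of every library, so it carried no ranking and was not used. No read counts were used, so sequencing depth is unknown, no interval or floor that needs it is given, and a peak missing from a list may lie just under the authors' threshold. The labels name more than 1 type of sequencer but not which library ran on which, so no sequencing batch could be tested. The number of peaks per library, 42560 to 57243 on chromosomes 1 to 22, X and Y, stands in for depth. The 33 to 71 peaks per library elsewhere were left out.

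Peaks of all libraries that touched or overlapped were merged into 83397 regions with numpy (2.4.6) and pandas (2.3.3) in Python (3.11.15). A region was called detected in a library where a peak covered at least 1 bp of it. Within 1 time, a region was counted as gained with TNF when all 4 TNF libraries and none of the 4 untreated libraries held it, and as lost in the opposite case; knockdown against control was counted in the same way. Each count was compared with all 35 splits of the same 8 libraries into 4 and 4. Over all 16 libraries, regions held by 3 to 13 of them were tested with Fisher's exact test, 8 libraries against 8, with Benjamini-Hochberg adjustment. Regions were assigned to the nearest protein-coding gene body within 100 kb, at distance 0 where they overlapped, from the RefSeq gene table of assembly GRCh38.p14. That table gives gene starts and ends without strand, exons or untranslated regions, so a region is described only as inside or near a gene body. Exact permutation tests were two-sided and permuted whole libraries. All single-value tests and Fisher's tests used scipy (1.17.1).

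The covered length per gene was added after the data were examined. It is the number of bases under peaks within a protein-coding gene body and 10 kb on either side. Of 20037 genes, the 14432 with a mean of at least 1000 bp were kept. Values were log2(bp + 500), centred on each library's median gene, and fitted with limma (3.58.1, R 4.3.3) with 1 mean per group, a variance trend and Benjamini-Hochberg adjustment over genes; a threshold of 0.05 was used throughout. The effect of TNF at 1 time is the mean of its effects in the 2 arms, and the effect of knockdown the mean of its effects in untreated and treated cells. Interaction terms give the differences between arms and between times. A fold change is on the log2(bp + 500) scale, which understates the change of short covered lengths, and its error is limma's standard error (SE). Covered lengths are in kb as mean ± SD (n = 2). Covered length says how far peaks extend, not how strong they are, and neighbouring genes can share 1 peak; counts of genes in a comparison are therefore given with the number of separate loci, and other counts of genes include neighbours. Gene lists were tested with limma's camera at its preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 15 lists.

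The 15 lists, with 276 members, were fixed before the data were examined, as were the grouping, the region counts, the Fisher tests, the NF-kB list test, the enrichment test and the rule for named genes. They cover NF-kB subunits and feedback, chemokines and cytokines, adhesion and matrix remodelling, survival genes, the death pathway, the AP-1 family, the interferon response, antigen presentation, SIK and CREB, HDAC and MEF2, pancreatic and epithelial identity, mesenchymal genes, the cell cycle, leukocyte markers and housekeeping genes. The first 4 lists make up the 83 genes, called NF-kB target genes here, whose peaks were counted per 10000 peaks. The name is only a label, since the lists also hold members of the pathway itself and binding of NF-kB was not tested. For regions, the rule names list members with a gained or lost region, the nearest genes of the widest 8 gained and 5 lost regions, 10 regions with the smallest Fisher p (the first in genome order where p was tied), and SIK3, NFKBIA, TNFAIP3, CXCL8 and HDAC4 in any case. For covered length, the rule was set after the data were examined: the 8 higher and 5 lower genes with the smallest p, list members past the threshold, and the same fixed genes. From these, the text gives examples; some list members are not reported here by name, and counts still include them.

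Alternatives were a required overlap of 50%, merging of peaks up to 200 bp apart, autosomes alone, lists shortened to their widest 42560 peaks, a gene distance of 10 kb, another enrichment background, TNF regions held by at least 3 of 4 libraries, a replicate block and leaving out each library in turn. For covered length they were the gene body alone, a pseudocount of 100 bp, scaling to the total covered length, peaks counted as at most 5 kb and no filter. Both tests across many features were tested on simulated data. With 200 of the 14432 genes changed in simulations built on the TNF comparison at 4 h, limma recovered a mean of 81.2% of 1.5-fold and 94.4% of 2-fold changes over 20 simulations, and 4.54% of calls were false. That share describes the simulated data only. Counts from relabelled real libraries are given with the other splits below. With 500 of 25000 regions set to be held by 95% of libraries on one side and 5% on the other, the Fisher test of 8 against 8 libraries recovered 44.4%, with 1 false call. No genome sequence was used, so the planned motif tests with 17 motifs were not run, and distances to transcription start sites were replaced by distances to gene bodies. Figures were drawn with matplotlib (3.10.9).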

Results

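The series asked how SIK3, a kinase of the salt-inducible kinase family, bears on the response of tumour cells to TNF, a cytokine that activates the transcription factor NF-kB through its receptors. ATAC-seq peak lists from PANC-1 cells were compared between TNF-treated and untreated cells and between SIK3-knockdown and control cells, at 4 h and 24 h, with 2 libraries in each of the 8 groups. The lists held 42560 to 57243 peaks and covered 34.67 to 45.83 Mb of hg38. Group means ran from 44110 ± 1949 peaks (SD, n = 2) in TNF-treated knockdown cells at 24 h to 55607 ± 2314 in TNF-treated control cells at 4 h. The most unequal replicates were the TNF-treated knockdown libraries at 4 h, with 54506 and 42560 peaks. Neither TNF nor knockdown moved the number of peaks or the number of peaks of 5 kb or wider beyond the spread between libraries at either time (8 exact permutation tests, 4 libraries against 4, smallest p = 0.0857, adjusted p = 0.343). Of the 83397 merged regions, 35.4% were held by all 16 libraries and 18.1% by a single library, and 57.1% overlapped a protein-coding gene. For pairs of libraries, the regions held by both were taken as a fraction of those held by either (Jaccard index), whatever their width. This fraction had a median of 0.778 between replicates, 0.743 between TNF-treated and untreated libraries and 0.723 between knockdown and control libraries.

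TNF for 4 h lengthened the accessible stretches at genes of the NF-kB response. TNFAIP3 (chromosome 6, 137866349 to 137883312), which encodes the deubiquitinase A20 that limits NF-kB signalling, rose 2.02-fold in covered length over both arms (log2 change 1.01 ± 0.06 SE, adjusted p = 2.37e-05, limma). In control cells it went from 2.35 ± 0.029 kb to 7.11 ± 0.294 kb, and in knockdown cells from 1.84 ± 0.313 kb to 3.15 ± 0.082 kb. TNIP1, a partner of A20, rose 2.37-fold (adjusted p = 0.000305), MAFF, a small MAF transcription factor, 2.60-fold (adjusted p = 0.00135), and CD40, a receptor of the TNF receptor family, 1.78-fold (adjusted p = 0.000141). BBC3 (chromosome 19, 47220824 to 47232860), which encodes the pro-apoptotic protein PUMA, fell the most of the named genes, with a log2 change of -2.97 ± 0.11 (adjusted p = 4.07e-07). Its peak of about 3.5 kb in untreated control cells (3.55 ± 0.0870 kb covered) was missing from all 4 TNF libraries at 4 h. Whether the chromatin closed or the peak lists dropped this peak is left open below.

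Of the 14432 genes tested at 4 h, 300 at 225 loci rose with TNF and 43 at 34 loci fell. Scaled to the total covered length instead of the median gene, 203 rose and 88 fell, a share of 69.8% higher in place of 87.5%. Counting gene bodies without flanks, 190 genes changed in place of 343. Of 100 labellings of the same libraries, the real one included, 6 gave counts as large, 2 of which follow another factor of the design, so chance is not excluded for this count. Among the chemokines and cytokines, 5 of 18 tested members rose, none fell and 13 did not pass, with 7 higher when adjusted over the list alone. They included CX3CL1, a chemokine that attracts T and NK cells (2.01-fold, 2.47 ± 0.359 kb to 4.86 ± 0.511 kb in control cells), IL32 (1.77-fold) and CSF1, the growth factor of macrophages (1.84-fold over both arms). CSF1 rose in control cells and not in knockdown cells. The list rose as a group (camera adjusted p = 4.25e-06, and adjusted p = 0.0182 with an estimated correlation). NF-kB subunits and feedback genes rose too, with 3 of 21 members past the threshold (7 when adjusted over the list alone; adjusted p = 0.000185, and adjusted p = 0.0152 with an estimated correlation). Antigen presentation genes rose (2 of 15, and 2 when adjusted over the list alone, adjusted p = 4.25e-06, and adjusted p = 0.0152 with an estimated correlation), among them B2M, the light chain of MHC class I (2.17-fold), and TAP2, a peptide transporter (1.30-fold). The B2M call ended when the gene body was counted without its flanks (adjusted p = 0.277).

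Adhesion and matrix remodelling genes rose at 4 h (2 of 14, and 4 when adjusted over the list alone, adjusted p = 0.000403, and adjusted p = 0.0182 with an estimated correlation). They were led by LAMB3, a laminin chain (2.17-fold, 0.964 ± 0.225 kb to 3.43 ± 0.0318 kb in control cells), and ITGB6, an integrin chain (1.45-fold). With the gene body alone that list no longer passed (adjusted p = 0.274). Survival genes passed with the preset correlation (2 of 12, and 3 when adjusted over the list alone, adjusted p = 0.000185) but not otherwise (adjusted p = 0.207 with an estimated correlation). The same held for the interferon response (1 of 14, and 1 when adjusted over the list alone, adjusted p = 0.0176, and adjusted p = 0.244 with an estimated correlation). The other 9 lists did not pass. MAFF was the 1 AP-1 family member of 11 that rose (adjusted p = 0.167 for the list), and CCNE1, which encodes cyclin E1, the 1 cell cycle member of 22 (1.34-fold; adjusted p = 0.298). SIK2 was the 1 SIK and CREB member of 16 (adjusted p = 0.163), and 2 of 13 housekeeping genes rose, among them GAPDH (adjusted p = 0.298). No member passed among 19 death pathway genes (adjusted p = 0.996), 16 HDAC and MEF2 genes, 19 pancreatic and epithelial identity genes and 16 mesenchymal genes (each adjusted p = 0.298), or 11 leukocyte markers (adjusted p = 0.405).

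The call at GAPDH (adjusted p = 0.211) ended with peaks counted as at most 5 kb. The SIK2 call ended with the gene body alone (adjusted p = 0.972). It also ended without replicate 3 (adjusted p = 0.0597) of untreated control cells, replicate 1 (0.0507) or 3 (0.064) of TNF-treated control cells, replicate 3 (0.0648) of untreated knockdown cells or replicate 3 (0.0558) of TNF-treated knockdown cells, all at 4 h.

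**Figure D1:**
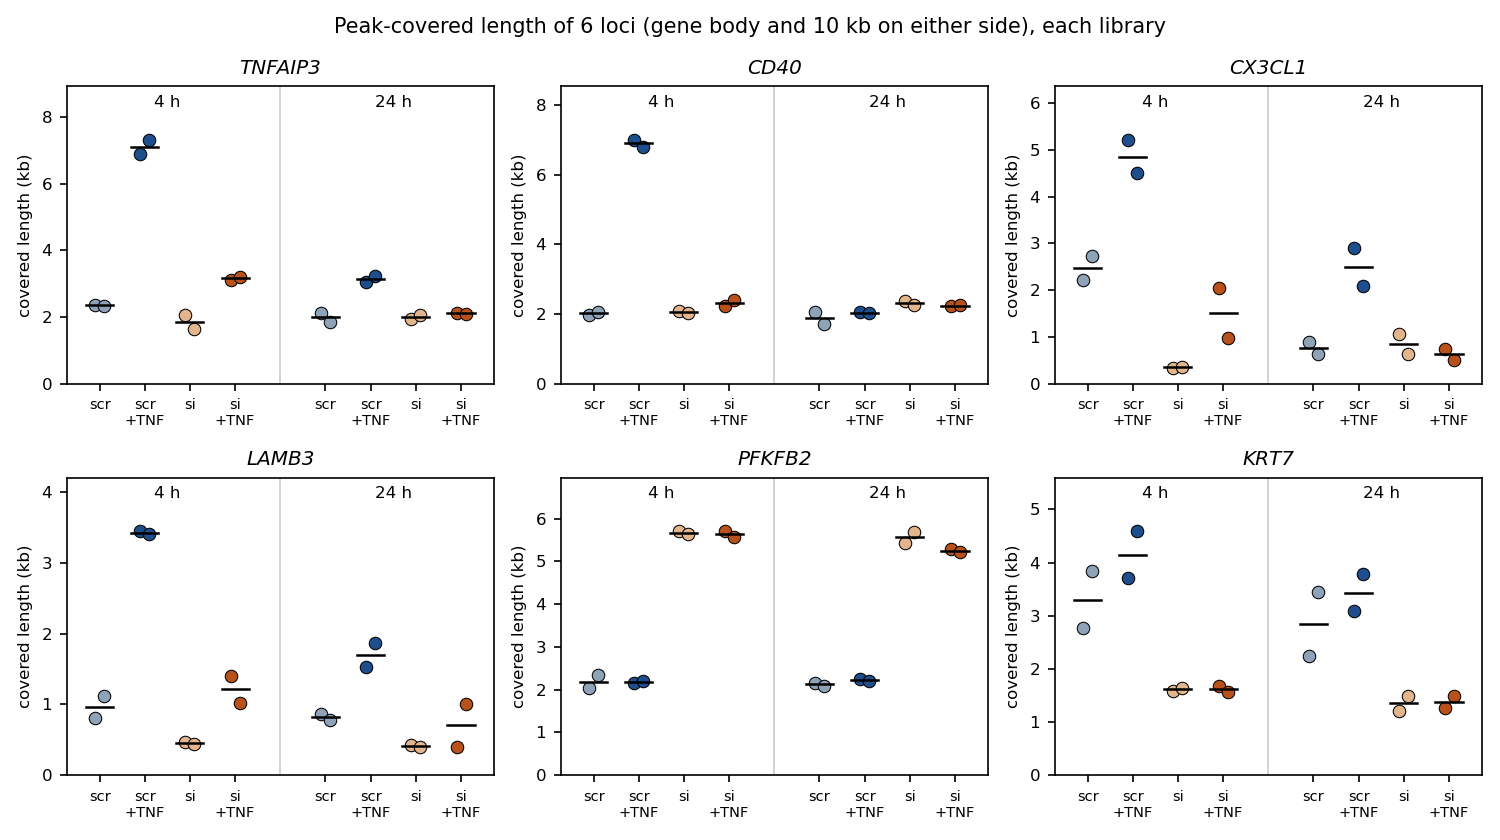
Bases covered by peaks (kb, vertical axis) in the gene body and 10 kb on either side of TNFAIP3, CD40, CX3CL1, LAMB3, PFKFB2 and KRT7, for the 8 groups along the horizontal axis; each point is a library and each line the mean of 2 libraries. TNFAIP3 reaches 7.11 kb in TNF-treated control cells at 4 h against 3.15 kb in TNF-treated knockdown cells, and PFKFB2 lies at 5.67 kb in untreated knockdown cells against 2.18 kb in untreated control cells.

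At the level of single regions, 346 were gained with TNF at 4 h in both arms and 51 were lost. The gained regions lay near NF-kB target genes more often than other regions held by 4 of the 8 libraries, 7 of 346 (2.02%) against 20 of 3950 (0.506%; odds ratio 4.06, Fisher's exact p = 0.00447). They lay near CXCL8 (chromosome 4, 73725985 to 73726399, 14169 bp from the gene), a neutrophil chemokine, CCL2 (chromosome 17, 34238461 to 34239518), a monocyte chemokine, TNFAIP3 (chromosome 6, 137832152 to 137832452), LAMB3 (chromosome 1, 209655551 to 209656246), MMP10, SERPINE2 and XIAP. Of the 51 lost regions, 3 lay near such genes, BCL3, BIRC3 and TNFAIP3 (odds ratio 10.99, Fisher's exact p = 0.00377). A region gained near ATF3 (chromosome 1, 212561418 to 212561960), a stress-response transcription factor, was held by all 4 TNF libraries at 4 h and by none of the other 12. Of the 15 lists taken singly, NF-kB subunits and feedback genes passed for the lost regions (2 of 51, adjusted p = 0.0419) and no other list did for gained or lost regions. With genes assigned within 10 kb, that list no longer passed (1 of 51, adjusted p = 0.178). Nor did the enrichment of gained regions near all NF-kB target genes (odds ratio 3.83, Fisher's exact p = 0.066). Without 1 library the 346 gained regions became 572 (untreated control, replicate 3) or 973 (TNF-treated knockdown, replicate 3). The 51 lost regions became 98 or 86 (untreated control, replicates 1 and 3), 120 or 81 (TNF-treated control), 89 or 126 (untreated knockdown) or 165 (TNF-treated knockdown, replicate 1). With lists of equal length, 230 regions were gained and 105 lost.

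Peaks near NF-kB target genes also took a larger share of each list with TNF. At 4 h they made up 52.7 ± 3.20 per 10000 peaks in TNF-treated libraries and 46.6 ± 1.48 in untreated libraries (SD, n = 4, exact permutation p = 0.0286, the smallest that 70 arrangements allow). At 24 h the values were 48.2 ± 1.83 and 43.1 ± 0.574 (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0286 over the 2 times). The rise at 4 h was from 47.8 to 55.3 in control cells and from 45.3 to 50.1 in knockdown cells. The difference between the arms' rises, averaged over both times, was -2.54 per 10000 (exact permutation p = 0.218). Without 1 of the 4 untreated libraries at 4 h, the difference of 6.16 became 6.46 (control, replicate 1), 6.69 (control, replicate 3), 5.69 (knockdown, replicate 1) or 5.79 (knockdown, replicate 3). The call ended each time (exact permutation p = 0.0571), because another arrangement of the libraries gave a difference at least as large. The call at 4 h also ended with lists of equal length, although the difference was larger (8.987, exact permutation p = 0.0571).

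**Figure D2:**
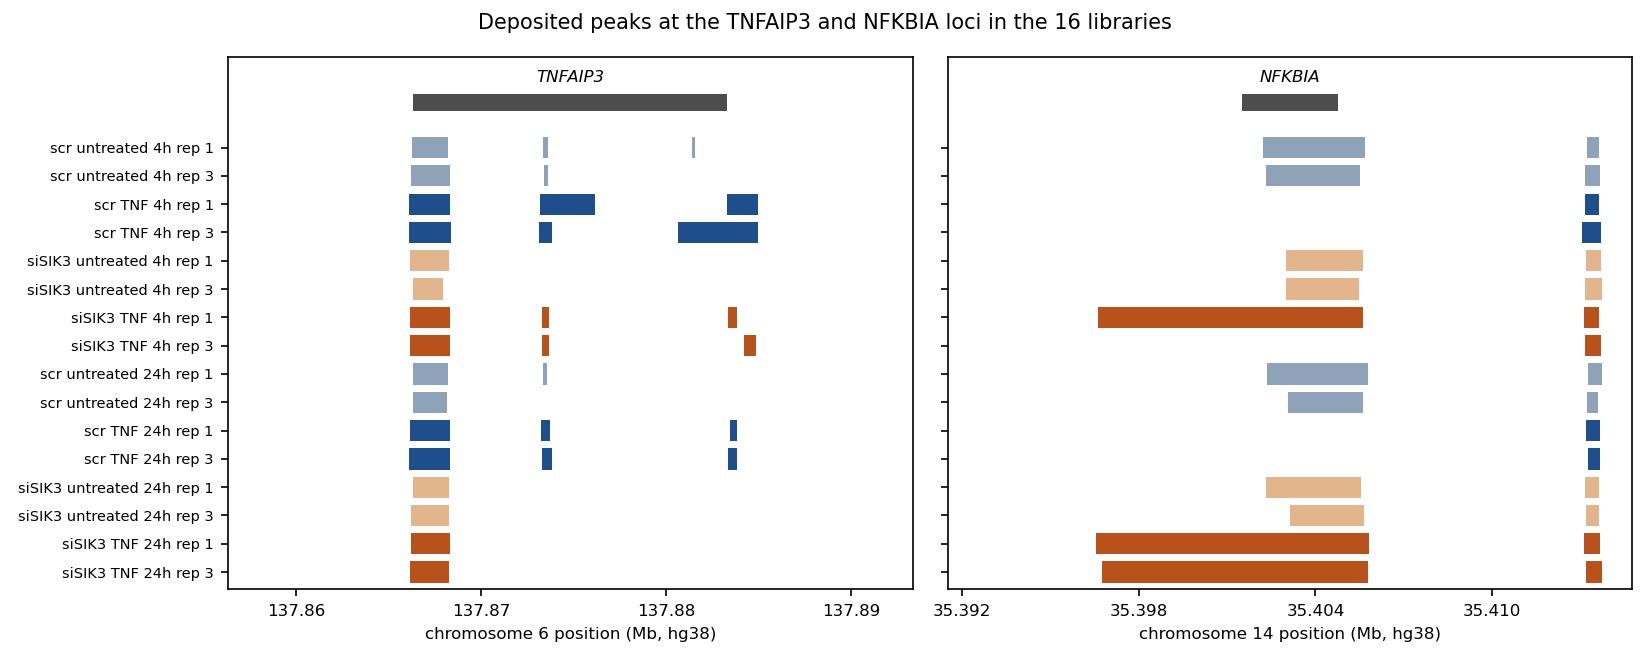
Deposited peaks (bars, 1 line per library, vertical axis) along chromosome position in Mb (horizontal axis) at TNFAIP3 and NFKBIA in the 16 libraries, with the gene body in grey. At TNFAIP3 the TNF-treated control libraries at 4 h hold peaks of 1659 and 4300 bp at the far end of the gene, and at NFKBIA the peak over the gene is absent from the 4 TNF-treated control libraries and 9012 to 9257 bp wide in 3 of the 4 TNF-treated knockdown libraries.

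NFKBIA (chromosome 14, 35401513 to 35404749), which encodes the NF-kB inhibitor IkB-alpha and is an early NF-kB target, did not pass in any comparison of covered length. Its covered length went from 3.79 ± 0.107 kb to 0.560 ± 0.0827 kb with TNF in control cells at 4 h and from 3.07 ± 0.0212 kb to 5.04 ± 6.37 kb in knockdown cells (log2 change over both arms -1.10 ± 0.51, adjusted p = 0.354). At 24 h the arms moved apart, from 3.42 ± 0.688 kb to 0.456 ± 0.0502 kb in control cells and from 3.33 ± 0.548 kb to 9.69 ± 0.182 kb in knockdown cells (difference between arms 3.47 ± 1.02, adjusted p = 0.36). The gene's peak, 3455 and 3200 bp wide in the untreated control libraries at 4 h, was absent from all 4 TNF-treated control libraries and from replicate 3 of TNF-treated knockdown cells at 4 h. It was 9012 bp wide in replicate 1 of that group and 9257 and 9042 bp wide in TNF-treated knockdown cells at 24 h. CXCL8 lay under the filter, with a mean of 666 bp covered. Without the filter it rose with TNF at 4 h (log2 change 0.71 ± 0.12, adjusted p = 0.00871) and was lower with knockdown (-0.77 ± 0.12, adjusted p = 0.00318).

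At 24 h TNF changed fewer genes, 88 at 74 loci higher and 65 at 53 loci lower. SAT1 (X chromosome, 23783173 to 23786210), the rate-limiting enzyme of polyamine breakdown, rose 3.64-fold (log2 change 1.86 ± 0.16, adjusted p = 0.000894). It went from 1.30 ± 0.193 kb to 6.24 ± 0.105 kb in control cells and from 1.32 ± 0.0170 kb to 6.22 ± 0.582 kb in knockdown cells. Its peaks are shared with the annotated gene LOC127933115, which has the same values. TNFRSF6B, which encodes a decoy receptor for ligands of the TNF family, rose 4.04-fold (adjusted p = 0.0185). That call ended without replicate 3 of TNF-treated control cells (adjusted p = 0.0507), replicate 1 of untreated knockdown cells (0.0727) or replicate 3 of TNF-treated knockdown cells (0.0551), all at 24 h. Of the pancreatic and epithelial identity genes, 3 of 19 fell, MUC1, a mucin, and the epithelial transcription factors GRHL2 and ELF3 (also 3 when adjusted over the list alone; camera adjusted p = 0.0374, and adjusted p = 0.131 with an estimated correlation). Adhesion genes passed as a group with none of 14 members past the threshold on its own (limma; median log2 change 0.11, adjusted p = 0.0374, and adjusted p = 0.131 with an estimated correlation). The NF-kB subunits and feedback genes had 2 of 21 members higher, TNIP1 and TRAF2 (4 when adjusted over the list alone; adjusted p = 0.0744), and TNFAIP3 did not pass (log2 change 0.28 ± 0.06, adjusted p = 0.0536).

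The count of 153 genes at 24 h rested on single libraries. Without replicate 1 or 3 of untreated control cells of 24 h it became 53 or 47, and of TNF-treated control cells of 24 h 68 or 17. In knockdown cells of 24 h, leaving out replicate 1 or 3 gave 6 or 60 (untreated) and 66 or 18 (TNF-treated). Either replicate of TNF-treated control cells of 4 h gave 81. Leaving out single libraries also ended the calls at MUC1 (14 of the 16 libraries, adjusted p = 0.0565 to 0.148), GRHL2 (10 libraries, 0.0508 to 0.133), ELF3 (15 libraries, 0.0596 to 0.165), TRAF2 (14 libraries, 0.0546 to 0.168) and TNIP1 (each of the 8 libraries of 24 h, 0.0503 to 0.11). Other settings ended the calls at MUC1 (peaks of at most 5 kb, 0.195), TNIP1 (gene body alone, 0.0525) and ELF3 (peaks of at most 5 kb, 0.0513, and total scaling, 0.0812). TRAF2 also ended with the gene body alone (0.0651), a pseudocount of 100 bp (0.0501), total scaling (0.0506), lists of equal length (0.0545) and no filter (0.0564). SAT1 stayed past the threshold in every alternative run.

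In regions, TNF gained 327 at 24 h and lost 200. Of the gained regions, 6 lay near NF-kB target genes (1.83% against 0.238% of comparable regions, odds ratio 7.84, Fisher's exact p = 0.000753), namely NFKBIA, CCL20, CD44, ITGA2, CFLAR and IER3. All 6 were also held without TNF at 4 h. Every untreated library of 4 h held those near NFKBIA, CCL20 and ITGA2, and at least 1 held each of the others. They were therefore gained only against the untreated libraries of 24 h. Of the lost regions, 3 lay near NF-kB target genes, NFKBIA, IL1B and BIRC3 (odds ratio 4.82, Fisher's exact p = 0.0367), and this no longer passed against all regions (p = 0.0655) or with genes within 10 kb (p = 0.36). The gained count became 507 without replicate 1 of TNF-treated control cells, 685 without replicate 3 of untreated knockdown cells and 567 without replicate 1 of TNF-treated knockdown cells. The lost count became 306 or 397 without replicate 1 or 3 of untreated control cells, 387 or 354 without replicate 1 or 3 of TNF-treated control cells, and 319 or 318 without replicate 1 or 3 of untreated knockdown cells.

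Regions that changed at 1 time were measured in the libraries of the other time, which took no part in choosing them. The 346 regions gained with TNF at 4 h were detected at 24 h in 48.8 ± 6.54% of cases in TNF-treated control libraries against 1.88 ± 0.613% in untreated ones (SD, n = 2). In knockdown libraries the values were 36.9 ± 11.7% and 6.65 ± 3.68%. The mean difference of 38.6 percentage points was larger than in any other arrangement (exact permutation p = 0.0286, adjusted p = 0.0327 over 8 tests, the smallest that 70 arrangements allow). The 327 regions gained at 24 h differed by 43.8 points at 4 h and the 51 lost at 4 h by -42.2 points at 24 h (exact permutation p = 0.0286 for each). Many of the 327 were also held without TNF at 4 h. Untreated libraries held 41.1 ± 23.6% (control) and 34.6 ± 1.30% (knockdown) of them, and TNF-treated libraries 83.5 ± 10.4% and 79.8 ± 10.8%. The 200 lost at 24 h differed by -21.4 points at 4 h, within the spread between libraries (exact permutation p = 0.114). Both times shared 32 gained regions, against 1.49 for independent sets. The latter value is a low mark, since it also counts regions not held by 4 of the 8 libraries of a time, which could not be gained. In covered length, 33 genes (not reduced to loci) were higher at both times against 1.83 for independent lists, and 78.7% of the 300 genes higher at 4 h had the same sign at 24 h. Both lists came from the same fit, with a variance per gene shared by the times, so they are not independent.

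**Figure D3:**
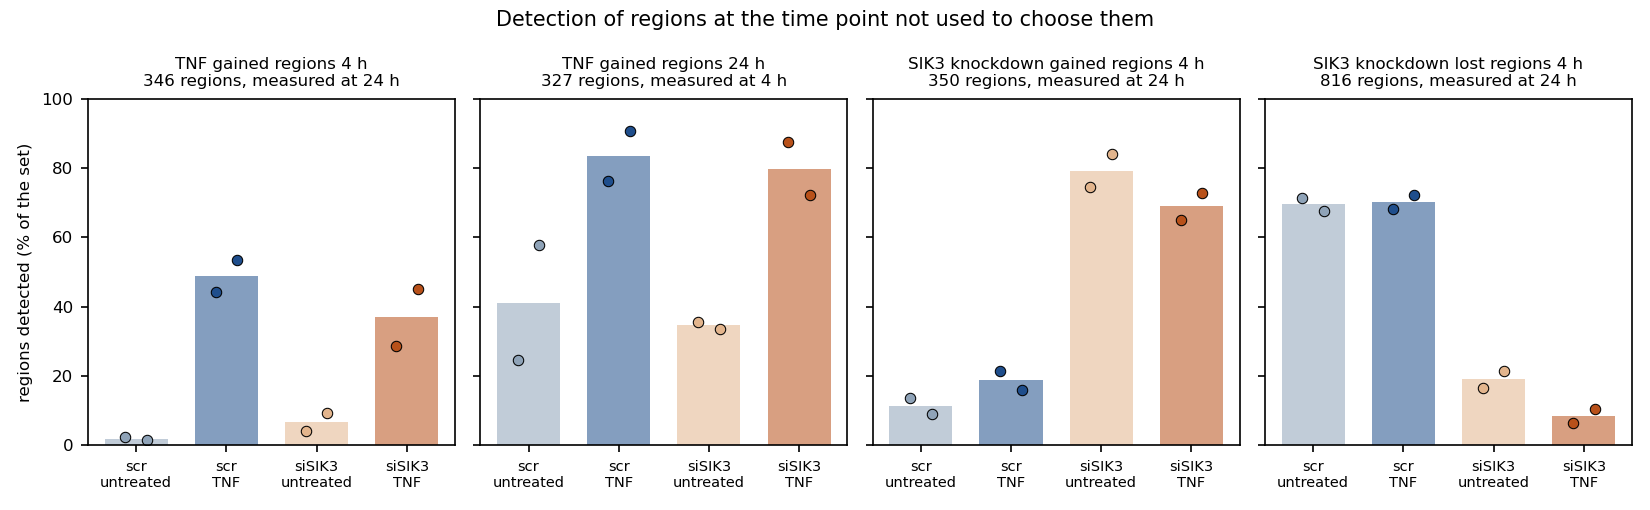
Share of each region set (percent, vertical axis) detected at the other time in the 4 groups of that time (horizontal axis), for 346 regions gained with TNF at 4 h, 327 gained with TNF at 24 h, 350 gained with SIK3 knockdown at 4 h and 816 lost with knockdown at 4 h; bars are means of 2 libraries and points are libraries. The TNF-gained set of 4 h lies at 48.8% in TNF-treated and 1.88% in untreated control libraries at 24 h, and the knockdown-lost set at 69.6% in untreated control and 18.9% in untreated knockdown libraries.

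SIK3 knockdown changed more genes than TNF did. At 4 h, PFKFB2 (chromosome 1, 207034416 to 207081027), an enzyme that sets the level of a glycolysis activator, rose 2.40-fold with knockdown (log2 change 1.26 ± 0.05, adjusted p = 2.7e-06), from 2.18 ± 0.211 kb to 5.67 ± 0.0537 kb in untreated cells. Its neighbour YOD1, a deubiquitinase gene that shares its peaks, rose 2.60-fold. KRT7 (chromosome 12, 52233243 to 52255853), a keratin of ductal epithelium, fell to 0.528 of the control value (adjusted p = 0.0024), from 3.30 ± 0.749 kb to 1.61 ± 0.0460 kb in untreated cells. GRHL2 (0.689, adjusted p = 0.0104), a transcription factor of epithelia, fell as well. RIPK1, a kinase of the TNF receptor complex, rose 1.2-fold (adjusted p = 0.00781).

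Knockdown at 4 h moved 769 genes at 523 loci higher and 823 genes at 719 loci lower. Scaled to the total covered length, 1187 were higher and 586 lower, a share of 66.9% higher in place of 48.3%. For gene bodies without flanks, 1060 changed in place of 1592. Among chemokines and cytokines, 5 of 18 fell and none rose (9 lower and 1 higher when adjusted over the list alone), among them CX3CL1 (0.336 of control), CSF1 (0.467) and IL32 (0.636). At CSF1 the arms differed mainly in TNF-treated cells. The list was lower as a group (camera adjusted p = 0.00173, and adjusted p = 0.12 with an estimated correlation). Adhesion and matrix remodelling genes had 6 of 14 lower (7 when adjusted over the list alone; adjusted p = 0.00173, and adjusted p = 0.0667 with an estimated correlation), including the laminin chain LAMB3 (0.555). Survival genes (1 of 12, and 3 when adjusted over the list alone, adjusted p = 0.0247, and adjusted p = 0.395 with an estimated correlation) passed with the preset correlation. So did antigen presentation genes (1 of 15, and 2 when adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.12 with an estimated correlation). NF-kB subunits and feedback genes had 5 of 21 lower (5 when adjusted over the list alone, and camera adjusted p = 0.0608 for the list), including TNFAIP3 (0.654) and TNIP1 (0.513). At TNFAIP3 the arms differed most in TNF-treated cells (7.11 ± 0.294 kb in control and 3.15 ± 0.082 kb in knockdown cells). Untreated cells had 2.35 ± 0.029 kb and 1.84 ± 0.313 kb. Of the epithelial identity genes, 3 of 19 were lower (also 3 when adjusted over the list alone; adjusted p = 0.0608). The count of 1592 genes became 979 without replicate 3 of untreated control cells, 893 without replicate 3 of TNF-treated control cells and 985 without replicate 3 of untreated knockdown cells.

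Whether SIK3 itself was lowered cannot be read from peak lists, which do not measure its transcript. The covered length of SIK3 (chromosome 11, 116843402 to 117098428) was 8.34 ± 2.18 kb in untreated control and 8.76 ± 1.79 kb in untreated knockdown cells at 4 h (adjusted p = 0.832). The values at 24 h were 8.01 ± 0.402 kb and 11.4 ± 0.0368 kb (log2 change over treated and untreated cells 0.35 ± 0.09, adjusted p = 0.0471). The call at 24 h ended without either TNF-treated control (adjusted p = 0.0631 and 0.0632) or either TNF-treated knockdown library of 4 h (0.0532 and 0.0533). Among libraries of 24 h, it ended without replicate 1 or 3 of untreated control (0.0892, 0.13), TNF-treated control (0.11, 0.102) or untreated knockdown cells (0.111, 0.107), or replicate 1 of TNF-treated knockdown cells (0.144). Without the filter it ended too (limma adjusted p = 0.0529), and in all it ended in 13 of the 23 alternative settings. HDAC4, a class IIa histone deacetylase and a known SIK substrate, did not pass in any comparison (adjusted p = 0.376 for knockdown at 4 h and 0.672 at 24 h).

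At 24 h knockdown moved 420 genes at 313 loci higher and 461 genes at 416 loci lower. Scaled to the total covered length, 469 were higher and 365 lower, a share of 56.2% higher in place of 47.7%, so the direction of the majority depends on the scaling. Gene bodies without flanks gave 544 in place of 881. PFKFB2 (2.04-fold, adjusted p = 7.59e-06) and YOD1 (2.28-fold) were higher again, and KRT7 (0.476 of control, adjusted p = 0.00224), LAMB3 (0.558, adjusted p = 0.00923) and TNFAIP3 (0.783, adjusted p = 0.00763) lower again. At TNFAIP3 the untreated arms were alike (1.99 ± 0.2 kb in control and 2 ± 0.0884 kb in knockdown cells). The arms differed in TNF-treated cells (3.14 ± 0.127 kb and 2.11 ± 0.0148 kb). TRAF2, an adaptor of TNF receptors, fell to 0.631 (adjusted p = 0.00428), and TSHZ3, a zinc finger transcription factor, rose 2.74-fold (0.580 ± 0.0629 kb to 2.88 ± 0.00778 kb in untreated cells). BBC3 fell to 0.119 of the control value (log2 change -3.07 ± 0.11, adjusted p = 2.93e-07), its peak being absent from all 4 knockdown libraries at 24 h and present in all 4 control libraries. Here too, a peak dropped from the peak lists is not excluded as the reason. No list passed at 24 h (lowest camera adjusted p = 0.3, and adjusted p = 0.605 with an estimated correlation). The count of 881 genes became 438 or 489 without replicate 3 of untreated or TNF-treated control cells of 24 h. It became 552 or 511 without replicate 1 or 3 of untreated knockdown cells and 441 or 542 without replicate 1 or 3 of TNF-treated knockdown cells, all of 24 h. Between the times, 217 genes were higher and 250 lower with knockdown at both (not reduced to loci), against 22.4 and 26.3 for independent lists, and 91.9% of the 823 genes lower at 4 h had the same sign at 24 h. As with TNF, the lists of both times share each gene's variance and are not independent.

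Knockdown gained 350 regions and lost 816 at 4 h, and gained 363 and lost 544 at 24 h, over treated and untreated cells. With lists of equal length the counts at 4 h were 586 gained and 482 lost, so which direction holds more regions there depends on list length. With an overlap of 50% the gained count at 24 h was 730. Gained at both times was a region of 7739 bp (chromosome 1, 3771589 to 3779327) that spans SMIM1, LRRC47 and CCDC27. Lost at both were a region of 9066 bp inside TNS3 (chromosome 7, 47533511 to 47542576), a focal adhesion gene, and 1 of 494 bp inside FN1, the fibronectin gene. Regions inside CDH1, which encodes E-cadherin (chromosome 16, 68760708 to 68761270), and GRHL2 were lost at 4 h. No gene list was enriched among these regions (smallest p of the 83 NF-kB target genes 0.386 in Fisher's exact tests). Of the 816 regions lost at 4 h, control libraries held 69.6 ± 2.69% (untreated) and 70.2 ± 2.86% (TNF) at 24 h. Knockdown libraries held 18.9 ± 3.55% and 8.27 ± 2.86%, a difference of -56.2 points (SD, n = 2, exact permutation p = 0.0286). The 350 gained differed by 59.1 points. Both times shared 76 gained and 158 lost regions, against 2.03 and 7 for independent sets, low marks for the same reason as with TNF. Without 1 library the 350 became 664 (untreated knockdown, replicate 3) or 630 (TNF-treated knockdown, replicate 3). The 816 became 1472 (untreated control, replicate 1) or 1230 (TNF-treated knockdown, replicate 1), and the 363 became 602 (untreated knockdown, replicate 1) or 562 (TNF-treated knockdown, replicate 1).

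Over all 16 libraries, Fisher's exact test called 772 of 25270 regions for knockdown, 254 held more often in knockdown and 518 in control libraries. The smallest p was shared by 234 regions, held by all 8 libraries of one arm and none of the other (Fisher's exact p = 0.000155, adjusted p = 0.0168). The first 10 of these in genome order, all on chromosome 1, include regions inside MEGF6 (chromosome 1, 3610676 to 3614362) and DLGAP3 held by knockdown libraries, and inside LZIC (chromosome 1, 9929373 to 9929779), VPS13D and ARHGEF10L held by control libraries. For TNF the same Fisher's exact test called 0 regions (smallest adjusted p = 0.101), with 1671 at an unadjusted p under 0.05. Of these, 39 had the smallest p, being held by all 8 libraries of one side and none of the other.

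The response to TNF differed between the arms at 4 h for 218 genes. It was smaller in knockdown cells for 75 genes at 69 loci and larger for 143 genes at 80 loci. The count was 102 with the gene body alone. Counts as large came from 6 of 100 labellings, the real one included, and 3 of the 6 follow another factor of the design, so chance is not excluded. CD40 (chromosome 20, 46118314 to 46129858) went from 2.01 ± 0.0728 kb to 6.91 ± 0.139 kb in control cells and from 2.05 ± 0.0318 kb to 2.31 ± 0.112 kb in knockdown cells (log2 difference -1.33 ± 0.12, adjusted p = 0.000555). TNFAIP3 (-0.68, adjusted p = 0.0155), TNIP1 (-1.29, adjusted p = 0.0155), CSF1 (-1.80, adjusted p = 0.0136) and ITGB6 (-1.24, adjusted p = 0.00485) also had smaller responses in knockdown cells. CSF1 went from 1.72 ± 0.178 kb to 7.44 ± 0.00141 kb in control cells and was 1.45 ± 0.610 kb and 1.38 ± 0.491 kb in untreated and TNF-treated knockdown cells. Without replicate 3 of TNF-treated control cells the calls at TNFAIP3 (adjusted p = 0.0583), TNIP1 (0.0534) and CSF1 (0.0533) ended, as did TNFAIP3 without replicate 3 of untreated control cells (0.0511), and the count of 218 became 130. ATF4, a transcription factor of the stress response, went from 2.84 ± 0.168 kb to 2.68 ± 0.0912 kb in control cells and from 2.94 ± 0.430 kb to 13.5 ± 0.575 kb in knockdown cells (log2 difference 2.19, adjusted p = 0.00016). With the gene body alone it did not pass (adjusted p = 0.0756).

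As a group, antigen presentation genes responded less in knockdown cells at 4 h (camera adjusted p = 0.00034, and adjusted p = 0.0428 with an estimated correlation). Of its 15 members, TAP2 passed alone, and 2 passed when adjusted over the list alone. The lists that follow passed with the preset correlation only. Chemokines and cytokines had 1 of 18 members lower, and 4 when adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.252 with an estimated correlation). Adhesion genes had 1 of 14 lower, and 1 when adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.0788 with an estimated correlation). The interferon response had none of 14 by limma, and 2 when adjusted over the list alone (adjusted p = 0.0448, and adjusted p = 0.347 with an estimated correlation). With the gene body alone these 4 lists did not pass (adjusted p = 0.175 for antigen presentation, 0.812 for chemokines, 0.532 for adhesion and 0.812 for interferon). The TAP2 call (log2 difference -0.66, adjusted p = 0.0188) ended without replicate 1 or 3 of untreated control cells (0.0576, 0.0537), replicate 3 of TNF-treated control (0.0709) or untreated knockdown cells (0.0589), or replicate 1 of TNF-treated knockdown cells (0.0507). In all, the TAP2 call ended in 6 of the 23 alternative settings. Tested within control cells alone, antigen presentation genes rose with TNF at 4 h (camera adjusted p = 2.2e-09, and adjusted p = 0.00311 with an estimated correlation), and within knockdown cells they did not pass (adjusted p = 0.593).

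At 24 h, 4 genes at 4 loci differed in response between the arms, all with a smaller response in knockdown cells (1134 genes at an unadjusted p under 0.05): BCL9L, FST, SRGAP2 and TNFRSF1B, the gene of TNF receptor type II. Of 100 labellings, the real one included, 15 gave counts as large, 4 of which follow another factor, so chance is not excluded. The count was 19 with the gene body alone and 7 with lists of equal length. TNFRSF1B went from 1.53 ± 0.419 kb to 4.12 ± 0.653 kb in control cells and from 2.24 ± 0.0898 kb to 1.21 ± 0.0106 kb in knockdown cells (log2 difference -1.85 ± 0.23, adjusted p = 0.0342). That call ended without replicate 1 or 3 of TNF-treated control cells of 4 h (adjusted p = 0.0622, 0.0632) or of 24 h (0.053, 0.117). It also ended without replicate 1 or 3 of untreated knockdown cells (0.11, 0.116) or without replicate 3 of TNF-treated knockdown cells (0.0657) of 24 h. In all, the TNFRSF1B call ended in 8 of the 23 alternative settings. The calls at FST and SRGAP2 ended without several of the same libraries, and the one at BCL9L with peaks counted as at most 5 kb (adjusted p = 0.42).

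In regions, 6079 were held by at least 2 of the 4 TNF libraries and no untreated library at 4 h. TNF-treated control libraries held 86.6 ± 0.326% of them and TNF-treated knockdown libraries 26.5 ± 11.9% (SD, n = 2). At 24 h, 2966 such regions were held at 67.8 ± 5.56% and 52.7 ± 9.78%. The matching regions held by untreated libraries alone also favoured control cells at 4 h, with 70.1% against 41.0% of 1346 regions, but not at 24 h, with 55.4% against 62.9% of 2580. The mean difference over both times was -37.5 percentage points (exact permutation p = 0.0556, the smallest that 36 arrangements allow, so the test could not reach the threshold). With lists of equal length the difference at 24 h turned to 9.27 points. Without replicate 1 or 3 of TNF-treated control cells the difference at 4 h was -3.57 or -0.978 points, and that at 24 h 20.3 or 32.0 points. Within control cells TNF gained 5546 regions and lost 1291 at 4 h, and gained 2834 and lost 1250 at 24 h, counts of 2 libraries against 2. Within knockdown cells it gained 1634 and lost 934 at 4 h, and gained 1479 and lost 2939 at 24 h. Another split of the 4 knockdown libraries of 4 h gave 3015 regions, so the 2 counts there lie within the spread between libraries. With lists of equal length, control cells gained 3347 and lost 2026 at 4 h, and knockdown cells lost 1852 at 24 h. Counts of genes by covered length did not all follow this order. In control cells, TNF moved 217 genes at 194 loci higher and 30 at 24 loci lower at 4 h, and 15 at 14 loci higher and 2 at 2 loci lower at 24 h. In knockdown cells, it moved 221 genes at 121 loci higher and 55 at 44 loci lower at 4 h, and 50 at 37 loci higher and 63 at 50 loci lower at 24 h.

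Time alone had little effect on detection in untreated cells: 20 regions were gained and 47 lost at 24 h against 4 h over both arms. In covered length, the response to TNF was higher at 24 h for 4 genes at 4 loci and lower for 14 at 12 loci. Among them were TNFAIP3 (log2 difference -0.74, adjusted p = 0.00724) and CD40 (-0.83, adjusted p = 0.00528), with a smaller response at 24 h. Without the filter, 28 genes differed in place of 18. The effect of knockdown was higher at 24 h for 14 genes at 11 loci and lower for 24 at 15 loci. Among them was NDRG2 (1.54, adjusted p = 0.000101), higher with knockdown at 24 h (1.46 ± 0 kb to 6.04 ± 0.442 kb in untreated cells).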

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

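The values below were set aside because an effect differed between the arms or between the times. The covered length per gene, the relabelled model, the limit on wide peaks, the test of missing wide peaks and the splits of the TNF and knockdown region counts were chosen only after the data had been seen. Nothing was set aside for a library far from its group, since groups of 2 do not allow that test.

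The response to TNF at 4 h differed between knockdown and control cells for 218 genes. It was smaller in knockdown cells, in log2 units, at CD40 (-1.33), SLC2A6 (-1.31), PDE4B (-1.15), COG6 (-1.33), DHRS12 (-1.06), CSF1 (-1.80), ITGB6 (-1.24), TNIP1 (-1.29), TAP2 (-0.66) and TNFAIP3 (-0.68). It was larger at METTL23 (2.05) and its neighbour JMJD6 (2.46), TRNAU1AP (2.87), ATF4 (2.19) and its neighbour RPS19BP1 (1.89), HSPA1L (1.30), RPL28 (2.64), TRIM72 (2.23) and GAPDH (1.83). Alternatives ended the calls at PDE4B (lists of equal length, adjusted p = 0.167), DHRS12 (0.0756) and HSPA1L (0.885; both gene body alone), and JMJD6 (0.3) and RPL28 (0.609; both peaks of at most 5 kb).

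At 24 h the response differed for 4 genes, BCL9L (-2.64), FST (-1.55), SRGAP2 (-1.18) and TNFRSF1B (-1.85). The count became 18 without replicate 1 of untreated control cells, 1 without replicate 3 of untreated knockdown cells and 27 or 9 without replicate 1 or 3 of TNF-treated knockdown cells of 24 h. Without a library of 4 h it became 10 (untreated control), 2 (TNF-treated control), 14 (untreated knockdown) or 15 (TNF-treated knockdown), the same for both replicates. FST and SRGAP2 ended without replicate 1 or 3 of TNF-treated control cells of 4 h (adjusted p = 0.0622, 0.0632), replicate 1 of untreated control cells (0.0508 for both genes) or its replicate 3 (0.0765 and 0.0799). The same held without replicate 1 (0.11 for both) or 3 (0.116 and 0.105) of untreated knockdown cells and replicate 3 of TNF-treated knockdown cells (0.0657 and 0.0688). FST also ended without replicate 1 of TNF-treated control cells (0.0763), and SRGAP2 without replicate 3 (0.117).

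The response to TNF differed between 24 h and 4 h for 18 genes. It was higher at 24 h for BBC3 (3.20), BCL9L (1.19), TNS4 (0.47) and ZDHHC8 (0.99), and lower for TRNAU1AP (-1.45), CD40 (-0.83), TNFAIP3 (-0.74), SLC2A6 (-0.79) and CD83 (-0.71). The count became 34 or 40 without replicate 1 or 3 of untreated knockdown cells and 49 or 43 without replicate 1 or 3 of TNF-treated knockdown cells of 4 h, 31 without replicate 3 of untreated control cells and 30 without replicate 1 of TNF-treated control cells of 24 h. TNS4 ended without replicate 3 of TNF-treated control cells (adjusted p = 0.0504) or of untreated knockdown cells (0.0523) of 24 h. ZDHHC8 ended without replicate 3 of TNF-treated control cells (0.08) or replicate 1 of untreated knockdown cells (0.0537) of 4 h. Among libraries of 24 h, it ended without replicate 1 of untreated control cells (0.0781), replicate 3 of TNF-treated control cells (0.0535), replicate 1 or 3 of untreated knockdown cells (0.0525, 0.0766) or of TNF-treated knockdown cells (0.0688, 0.065). BCL9L (0.447) and TRNAU1AP (0.059) ended with peaks of at most 5 kb, and CD83 (0.0745) with the gene body alone.

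The effect of knockdown differed between the times for 38 genes. It was higher at 24 h for NDRG2 (1.54) and ARHGEF40, which overlaps it (1.70), BCL9L (1.17), C2orf81 (0.69) and its neighbour WDR54 (0.68), ROMO1 (0.70), CD40 (0.69) and ARID5A (0.53), and lower for BBC3 (-3.23), H2AX (-0.93), RPS19BP1 (-1.10), ATF4 (-1.07) and TRNAU1AP (-1.32). The count became 23 without replicate 3 of TNF-treated control cells and 64 or 63 without replicate 1 or 3 of TNF-treated knockdown cells of 4 h, and 24 or 20 without replicate 1 or 3 of untreated knockdown cells of 24 h. ARID5A ended without 10 of the 16 libraries (adjusted p = 0.0539 to 0.0883). With the gene body alone ROMO1 (0.44), H2AX (0.342) and ATF4 (0.338) ended, and with peaks of at most 5 kb TRNAU1AP (0.118). The effect of knockdown averages treated and untreated cells, so a change in a single group can produce such a difference. At CD40, TNF-treated control libraries of 4 h had 7.01 and 6.81 kb covered, and the highest other library had 2.39 kb.

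Fewer of the TNF regions were held by knockdown than by control libraries, and shorter peak lists in knockdown libraries could produce this without any biology. With all lists shortened to equal length, the difference averaged over both times was -20.26 percentage points, and in tests of each time chosen after the result was seen it was -49.79 at 4 h and 9.266 at 24 h. These values do not settle it, because the regions were chosen by the same TNF libraries, a rule that favours the more alike pair, and without replicate 1 or 3 of TNF-treated control cells the difference at 4 h was -3.57 or -0.978. Regions held by untreated libraries alone were also held less often by knockdown libraries at 4 h (41.0% against 70.1%), and more often at 24 h (62.9% against 55.4%), by the same rule and with the same limit. Whether TNF opened chromatin less without SIK3 is left open.

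The larger responses to TNF in knockdown cells at 4 h (143 genes at 80 loci) could come from very wide peaks that span several genes in the TNF-treated knockdown libraries. With each peak counted as at most 5 kb, 77 genes (53.8%) stayed past the threshold, and their median log2 difference went from 1.19 to 0.742 over all 143. The size of the pattern therefore depended in part on peaks wider than 5 kb. A peak counted as 5 kb can still be wider than in the other groups, and neighbouring genes still share it. This limit therefore cannot tell whether any of the pattern is free of wide peaks. Of the 75 genes with a smaller response, 62 (82.7%) stayed, with medians of -0.884 and -0.88.

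Several peaks were missing from whole groups, which closed chromatin, or a peak list that drops very wide or neighbouring peaks, might explain. The NFKBIA peak was absent from the TNF-treated control libraries and from replicate 3 of TNF-treated knockdown cells at 4 h. The BBC3 peak was absent from the TNF libraries at 4 h. At 24 h it was absent from the knockdown libraries, treated or not, and present in TNF-treated control cells (4258 and 5978 bp). Regions lost with TNF at 4 h lay within 10 kb of a peak that widened with TNF more often than other regions did (odds ratio 18.62, 95% interval 3.298 to 70.87), but only 3 of 51 did. Of regions held by at least 8 libraries, 20.8% of those with a mean peak width of 4 kb or more were missing from at least 1 library, against 7.56% of those of 2 to 4 kb (odds ratio 3.207, interval 2.449 to 4.177). The share was as high for narrow peaks of 500 to 1000 bp (21.1%). The BBC3 peak, with a mean width of 3994 bp, lies just under the cut of 4 kb, which was set after the data were seen. Its class therefore depends on where the cut was placed, and this test cannot decide whether width is the reason for its absence. Whether the lists or closed chromatin account for the missing peaks is left open.

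Whether chance could have grouped the libraries this way was tested with other splits, and every number of splits or labellings as large includes the real one. The knockdown counts of regions were the largest of 35 splits at both times: 350 gained and 816 lost at 4 h (1 of 35 as large, the next 346, the TNF split) and 363 gained and 544 lost at 24 h (1 of 35, the next 327, the TNF split). For TNF, 2 of 35 were as large for the 346 gained at 4 h, the 327 gained at 24 h and the 200 lost at 24 h, the other being the knockdown split (816 and 544). For the 51 lost at 4 h, 21 of 35 were, so chance is not excluded there. Between the times in untreated cells, 31 of 35 splits were as large for the 20 gained and 18 of 35 for the 47 lost (highest 747). Within an arm, 4 libraries allow only 3 splits, too few for a share under 0.05. The highest other counts there were 1278 (control, 4 h), 1127 (control, 24 h), 3015 (knockdown, 4 h) and 944 (knockdown, 24 h). The 3015 exceeds the 1634 regions gained and the 934 lost with TNF in knockdown cells at 4 h. Of 100 splits into 8 and 8, 1 had as many regions by the Fisher test as knockdown (772, highest other 0). For TNF the count was 0, so all 100 were as large by construction, and these splits say nothing about chance.

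For covered length, limma between groups of 4 called 259 genes for knockdown at 4 h (1 of 35 splits as large, highest other 5) and 490 at 24 h (1 of 35, highest other 5). For TNF it called 4 at 4 h (6 of 35, highest 259, the knockdown split, and otherwise 5) and 5 at 24 h (2 of 35, highest 490, the knockdown split, and otherwise 4). This simpler fit does not exclude chance for TNF at either time. In the model of 8 groups with the libraries of 1 time relabelled, 1 of 100 was as large for knockdown at 4 h (1592, highest other 305) and at 24 h (881, highest other 9). For TNF, 6 of 100 were as large at 4 h (343, highest 1176, and 436 among those that follow no other factor) and 6 at 24 h (153, highest 768, and 9 among those). For the difference between arms, 6 of 100 were as large at 4 h (218, highest 1074, and 230 among those that follow no other factor) and 15 at 24 h (4, highest 648, and 9 among those), so chance is not excluded for either difference, nor for the TNF count at 4 h.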

How the results depend on the processing

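Of 452 alternative values of the main results, 317 stayed on the same side or within the allowed range, 125 moved, 7 no longer passed and 3 reversed; of 4086 for single genes and lists, 3566 stayed, 516 no longer passed and 4 reversed. The cause was not tested except where stated. Lists of equal length, the gene body alone, the block and the limit on wide peaks for covered length were chosen after the data were seen. Depth is unknown, so peaks near the authors' threshold cannot be told from absent ones. Lists of equal length by score, only the stronger peaks by score, the looser NF-kB consensus, the narrower motif search and the regression with width and GC content were not run, as every score was the same and no genome sequence was used. Lists of equal length gave 230 regions gained and 105 lost with TNF at 4 h, 586 gained and 482 lost with knockdown at 4 h, 3347 gained and 2026 lost with TNF in control cells at 4 h and 1852 lost with TNF in knockdown cells at 24 h. They also gave a reversed detection difference of 9.266 points at 24 h, 8.987 peaks per 10000 for the NF-kB list at 4 h (exact permutation p = 0.0571) and 7 genes for the difference between arms at 24 h. An overlap of 50% gave 730 regions gained with knockdown at 24 h. Gene bodies alone gave 190 genes for TNF at 4 h, 1060 and 544 for knockdown at 4 h and 24 h, and 102 and 19 for the difference between arms. No filter gave 7 genes for that difference at 24 h and 28 for TNF between the times.

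Replicate numbers were not used to pair the samples in the main tests. The 28 correlations of replicate differences between groups ran from 0.001 to 0.096 (median 0.046). These are low but all positive, so a weak effect shared by libraries of the same replicate number is not excluded. With the replicate block, 234 regions in place of 772 were called by Fisher's test for knockdown. The NF-kB list difference was then 6.157 at 4 h and 5.167 at 24 h (exact permutation p = 0.0556, from fewer arrangements), and 8 genes differed between arms at 24 h. Reversed single values were SIK2 for TNF at 4 h (-0.014, gene body alone) and, with peaks of at most 5 kb, GAPDH for knockdown at 4 h (-0.002), BCL9L for knockdown at 24 h (-0.079) and BCL9L for knockdown between the times (-0.548).

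Leaving out 1 library can only raise region counts, by construction; the lone library left in a group is assumed to vary like the others in limma. Ranges were, for TNF in both arms, 383 to 973 gained and 62 to 165 lost at 4 h and 364 to 685 and 251 to 397 at 24 h; for knockdown 370 to 664 and 874 to 1472 at 4 h and 434 to 602 and 590 to 814 at 24 h. For TNF in control cells they were 6453 to 10054 and 2125 to 4603 at 4 h and 4236 to 6017 and 2374 to 4523 at 24 h, in knockdown cells 2238 to 7829 and 1254 to 3981 at 4 h and 2081 to 4011 and 4229 to 6293 at 24 h, and between times in untreated cells 27 to 72 and 68 to 177. Fisher's test gave 0 for TNF each time and 858 to 962 for knockdown. The detection difference ran from -83.65 to -0.978 at 4 h and from -51.77 to 31.99 at 24 h, reversing to 20.33 and 31.99 without replicate 1 or 3 of TNF-treated control cells, since the rule of 2 libraries then favours knockdown pairs. The NF-kB list difference ran from 4.893 to 7.205 and from 4.412 to 5.8. Genes by limma ran from 230 to 372 (TNF, 4 h), 6 to 139 (TNF, 24 h), 893 to 1479 (knockdown, 4 h), 438 to 928 (knockdown, 24 h), 130 to 234 and 1 to 27 (arms, 4 h and 24 h), 13 to 49 (TNF between times) and 20 to 64 (knockdown between times).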

Other observations

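Between the times, the effect of TNF on covered length was lower at 24 h than at 4 h for 7 lists with the preset correlation, and for none of them with an estimated correlation. Of lists that had risen at 4 h, these were chemokines and cytokines (camera adjusted p = 0.00475, and adjusted p = 0.0998 with an estimated correlation), antigen presentation genes (adjusted p = 0.00475, and adjusted p = 0.0564 with an estimated correlation) and NF-kB subunits and feedback genes (adjusted p = 0.026, and adjusted p = 0.086 with an estimated correlation). The interferon response (adjusted p = 0.0198, and adjusted p = 0.239 with an estimated correlation) and survival genes (adjusted p = 0.0363, and adjusted p = 0.344 with an estimated correlation), which had risen at 4 h with the preset correlation only, were also lower. Of lists without a call at 4 h, these were pancreatic and epithelial identity genes (adjusted p = 0.00475, and adjusted p = 0.0564 with an estimated correlation) and SIK and CREB genes (adjusted p = 0.0121, and adjusted p = 0.067 with an estimated correlation). With the gene body alone, the calls of the epithelial (adjusted p = 0.602), SIK and CREB (0.0561) and interferon (0.23) lists ended, and with peaks of at most 5 kb that of survival genes (0.123). Lists of equal length also ended the SIK and CREB call (0.107).

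The widest merged region spans 228357 bp of chromosome 19 (39332266 to 39560622), overlaps 13 protein-coding genes, among them ZFP36, and holds peaks in all 16 libraries, which cover 147.2 to 209.6 kb of it. CXCL8 had 1.98 ± 0.00141 kb covered in TNF-treated control cells at 4 h and 0.524 ± 0.0764 kb in TNF-treated knockdown cells, against 0.624 ± 0.282 kb and 0.343 ± 0.0453 kb untreated.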
